A study of Homo sapiens with 6 samples.

How the data were processed

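NGP neuroblastoma cells were grown in serum-containing medium and exposed for 12 h to OTSSP167 at 60 nM or to DMSO. Per the labels' protocols, RNA was extracted with TRIzol and sequencing libraries were made from total RNA with a SMARTer mRNA kit. The authors deposited 1 table for the whole series, which holds whole-number counts per gene symbol in 6 libraries, 3 per group, and no normalized values. Per the submitters' processing notes, the reads passed through FastQC 0.11.2, HISAT2 2.1.0 and StringTie 1.3.5 with the genome build GRCh38.p13. Which of these steps made the counts, the annotation release, the strand setting and any filter are not given in the sources used here. Reads of overlapping, antisense or near-identical genes may therefore be divided in an unknown way. Per the series design text, the submitters tested differential expression with DESeq2.

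The table has 19863 rows, all with a symbol and whole values, and 2881 of them are at 0 in the 6 libraries. The columns were matched to samples by group and number in their names, and 0 columns belonged to other samples. For 58 symbols that occur in more than 1 row, the row with the larger total kept the symbol and the other was tested under its own name. The files carry no coordinates, so chromosome positions were taken from GENCODE release 29 on GRCh38 by symbol, which matched 19231 rows (96.8%). Library totals were 50810126, 47403025 and 46230392 counts for DMSO replicates 1 to 3 and 39445832, 57460375 and 36401828 for OTSSP167 replicates 1 to 3. A chi-square statistic per gene between replicates was 93.6 to 110.8, where 1 is sampling noise alone, so no library was a copy of another. Counting error is small at this depth for genes above 10 CPM, and the spread between libraries sets the precision.

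The counts were analysed with edgeR 4.0.16 in R 4.3.3: filterByExpr for low counts, TMM scaling, a quasi-likelihood fit with robust dispersion and its F test of treatment with no other term, and Benjamini-Hochberg adjustment with a threshold of 0.05. A second test asked for a change beyond 1.5-fold (glmTreat). CPM values are scaled by the TMM factors. The standard error of a log2 fold change is its size divided by the square root of the F statistic. Gene lists were tested with camera in limma 3.58.1 on voom values, 2-sided, with a preset correlation between genes of 0.01, over 23 lists with 5 or more tested members. An estimated correlation and fry, which asks whether a list's own genes move one way without comparing them with other genes, were run beside it. List medians in the text are of edgeR's log2 fold changes.

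The groups, tests, alternatives and 24 gene lists were fixed before the data were examined; 777 of 784 list entries were found in the table. The genes named by rule are CAMKV, MELK, AURKB, MYCN and CREB1; the 6 largest rises and 6 largest falls that passed the test with at least 10 CPM on average and separated groups; and, from each list that passed camera or had at least 1 in 3 members called, the 2 members with the smallest p in the main direction and 1 in the other. From other lists with called members it is the member of smallest p. Some genes that this rule takes are not reported here. RPL27, NDUFA2, CHGA and 5 further gene lists with their members, given at the end, were chosen after their values were seen.

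Alternatives were DESeq2 1.42.0, limma-voom, 3 other scalings (DESeq2 size factors, upper quartile, library size only), no low-count filter, at least 1 CPM in the 6 libraries, a fold of 2, the replicate number as a block, and each library left out in turn. An analysis without genes whose libraries range over 2-fold within a group was added after seeing the data.

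The gene test was checked on simulated counts for the 14402 genes of the OTSSP167 comparison, with 50 genes each changed by 1.5-, 2-, 4- and 8-fold. With edgeR's shrunken dispersions it recovered 2, 8, 68 and 84% of them (1, 4, 34 and 42 genes), with 10 false calls. This low recovery led to a second simulation with unshrunken dispersions per gene, which recovered 16, 40, 76 and 82% (8, 20, 38 and 41 genes), with 5 false calls. Far fewer genes were changed in these simulations than the 6638 called in the data, which makes the adjusted threshold stricter. The recovered shares therefore do not measure recovery in the real comparison. In simulations with 1 list raised by 1.5-fold, camera called that list and 0 of the other 22 under either setting. The simulated genes were drawn independently of one another, 1 draw per setting. This check therefore could not show false list calls that come from correlation between genes.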

Results

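The transcriptome of NGP cells, an established MYCN-amplified human neuroblastoma line, was measured by mRNA sequencing after 12 h with OTSSP167 at 60 nM or with the solvent DMSO alone. OTSSP167 is a kinase inhibitor first described against MELK and named in the series title as an inhibitor of CAMKV, a kinase-like member of the calcium/calmodulin-dependent kinase family. Each group held 3 libraries, with totals of 46230392 to 50810126 counts in the DMSO group and 36401828 to 57460375 in the OTSSP167 group. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The question was which transcripts differ between treated and control cells. Levels are given as CPM scaled between libraries, mean ± SD with n = 3, and coordinates are those of GRCh38. CPM are relative to the counted reads of a library, so rises and falls are relative to other transcripts. A change in RNA per cell would not be seen.

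OTSSP167 changed a large part of the transcriptome within 12 h. Transcripts of cytosolic ribosomal proteins and replication-dependent histones rose as groups. Those of MYC and MYCN targets, adrenergic neuroblastoma regulators, neuronal genes, cholesterol synthesis, glycolysis and the mitochondrial genome fell. These 8 lists passed limma's camera test at its preset correlation, and they had adjusted p = 0.166 to 0.367 with an estimated correlation. MYCN itself fell from 7544 ± 99.9 to 4495 ± 17.8 CPM (n = 3). Of 14402 genes tested, 6638 passed edgeR's quasi-likelihood test after Benjamini-Hochberg adjustment, 3423 higher and 3215 lower with OTSSP167, and 7771 had an unadjusted p under 0.05. Tested against a change of 1.5-fold, 2826 genes passed, 1526 higher and 1300 lower. The larger part of this count was lower without OTSSP167 replicate 1 (1066 higher, 1100 lower), 2 (980 and 1041) or 3 (1067 and 1071). The 3 OTSSP167 libraries lay on one side of the 3 DMSO libraries in 8696 of the tested genes (60.4%). The share would be 10% if the 6 libraries were interchangeable, which is not known, as those of a group may share a culture. The first principal component held 65.1% of the variance and separated the groups. Spearman correlations across genes were 0.966 to 0.976 within groups and 0.911 to 0.916 between them.

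**Figure D1:**
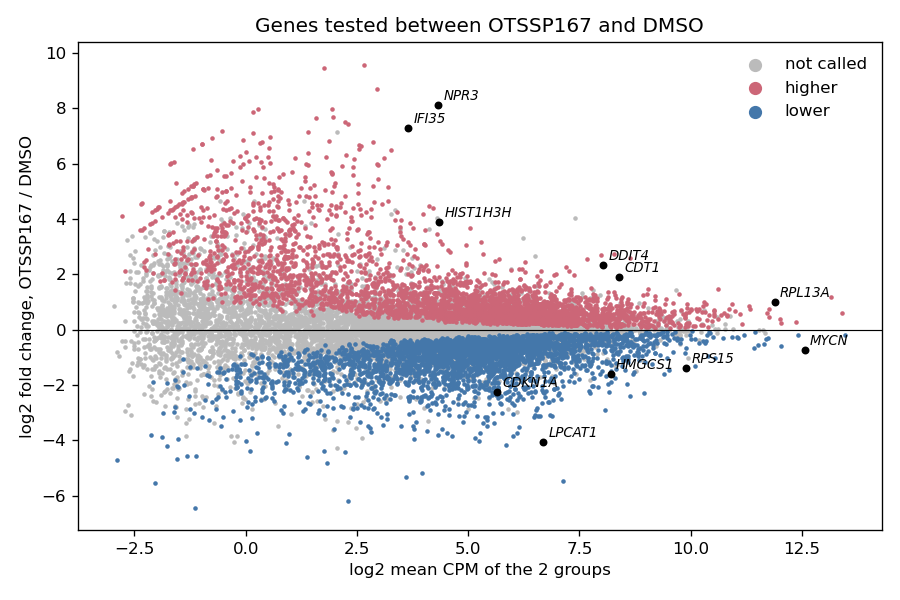
Each point is a gene, with the log2 mean CPM of both groups on the x axis and the log2 fold change of OTSSP167 over DMSO on the y axis. Genes that passed edgeR's test are red (higher) or blue (lower), named genes are black, and the plot holds the 14246 genes that were not at 0 in all libraries of a group.

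Among the kinases and transcription factors named in advance, MYCN and AURKB changed, while CAMKV, MELK and CREB1 did not pass the test. MYCN, the amplified oncogene of this line (chromosome 2, 15940564 to 15947007), fell by 0.75 on the log2 scale (SE 0.01, edgeR adjusted p = 5.74e-06). AURKB, a mitotic kinase (chromosome 17, 8204733 to 8210600), rose from 143.0 ± 1.84 to 271.5 ± 9.83 CPM (log2 fold change 0.92, SE 0.04, edgeR adjusted p = 6.24e-05). CAMKV (chromosome 3, 49857988 to 49870222) stood at 51.0 ± 25.5 CPM in DMSO and 15.1 ± 13.8 CPM in OTSSP167 (log2 fold change -1.75, SE 0.77, edgeR adjusted p = 0.118). Its single libraries ranged from 24.3 to 75.2 CPM in DMSO and from 6.39 to 31.1 CPM in OTSSP167, so the groups overlapped. CAMKV passed with DESeq2 (-1.73, adjusted p = 0.0369) and in edgeR without OTSSP167 replicate 2 (-2.84, adjusted p = 0.0213); over all its alternatives the adjusted p ran from 0.0213 to 0.258. MELK (chromosome 9, 36572862 to 36677683) measured 26.6 ± 12.3 and 21.5 ± 17.1 CPM (log2 fold change -0.31, SE 0.72, edgeR adjusted p = 0.753), with an estimate of 0.11 without OTSSP167 replicate 3 (adjusted p = 0.899, in a range of 0.230 to 0.928 over its alternatives). CREB1, a transcription factor phosphorylated by CaM kinases (chromosome 2, 207529737 to 207603431), measured 66.3 ± 15.3 and 102.7 ± 20.5 CPM (log2 fold change 0.63, SE 0.23, edgeR adjusted p = 0.0721). CREB1 passed with DESeq2 (adjusted p = 0.0283), and in edgeR with upper-quartile scaling (0.0457) and without OTSSP167 replicate 3 (0.0484). Over all its alternatives the adjusted p ran from 0.0283 to 0.181. It also passed in edgeR without genes of scattered replicates (0.0394), a setting chosen after seeing the data. That setting removes genes by their spread in these same libraries, which can lower p-values, so this pass adds no support.

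**Figure D2:**
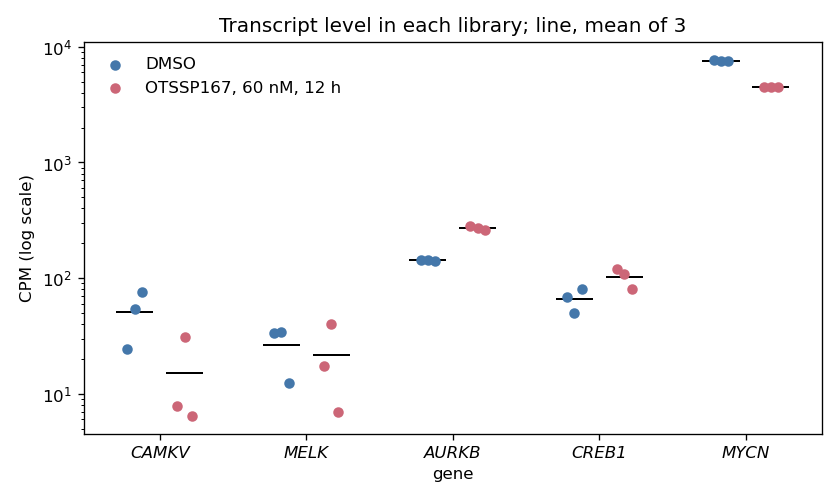
CPM on a log axis of CAMKV, MELK, AURKB, CREB1 and MYCN in each of the 3 DMSO (blue) and 3 OTSSP167 (red) libraries, with a black line at each group mean. The groups are apart for AURKB and MYCN, and overlap for CAMKV, MELK and CREB1.

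Of the 8 kinases named as OTSSP167 targets, 2 rose and 1 fell, the same numbers adjusted over the list alone, with a median log2 fold change of 0.16 and a mean of -0.24. GSG2, which encodes the histone H3 kinase haspin, rose by 0.47 on the log2 scale (edgeR adjusted p = 0.00364). BUB1, a spindle checkpoint kinase, fell from 100.9 ± 16.8 to 25.9 ± 10.8 CPM (log2 fold change -1.96, SE 0.33, edgeR adjusted p = 0.00629). In the calcium/calmodulin-dependent kinase family, 2 of 18 members rose and 4 fell (1 and 4 adjusted over the list alone). CAMK2N2, an inhibitor of CaM kinase II, fell by 1.49 (edgeR adjusted p = 0.00151) and CALM3 was 0.09 higher (adjusted p = 0.0252). The small CALM3 change did not pass without DMSO replicate 1 (adjusted p = 0.0634), DMSO replicate 3 (0.0567), OTSSP167 replicate 1 (0.0737) or OTSSP167 replicate 2 (0.0814), in a range of 0.000964 to 0.0848 over its alternatives. Of 30 CREB target and immediate early genes, 8 rose and 5 fell, the same adjusted over the list alone, with a median log2 fold change of -0.09 and a mean of 0.25. With upper-quartile scaling, 8 rose and 3 fell, and the median was 0.01. EGR1, an immediate early zinc finger factor, rose from 6.12 ± 1.04 to 42.4 ± 15.2 CPM (log2 fold change 2.79, SE 0.34, edgeR adjusted p = 0.00193). JUNB, an AP-1 subunit, rose by 1.05 and the nuclear receptor NR4A3 fell by 1.46. These 3 lists did not pass limma's camera test (adjusted p = 0.600 for the target kinases, 0.434 for the CaM kinase family and 0.860 for the CREB list).

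The largest rises among genes of at least 10 CPM were in genes under 2 CPM in DMSO. NPR3, the natriuretic peptide clearance receptor (chromosome 5, 32689070 to 32791724), rose from 0.142 ± 0.123 to 40.1 ± 12.3 CPM (log2 fold change 8.13, SE 0.90, edgeR adjusted p = 0.00145), on 20 and 5460 counts. IFI35, an interferon-induced gene (chromosome 17, 43006725 to 43014456), rose from 0.160 ± 0.0634 to 25.02 ± 0.589 CPM (log2 fold change 7.27, SE 0.30, edgeR adjusted p = 5.97e-05). IFI35 begins 3766 bp downstream of RPL27, a ribosomal protein gene on the same strand at 732 CPM over all libraries. KLHL35 rose by 4.45 on the log2 scale and ELFN2 by 4.19. MROH7-TTC4 (4.38) and ISY1-RAB43 (4.26) also rose, but these loci span neighbouring genes whose reads they share, so their values are uncertain. Among the largest falls was that of TMEM261 (chromosome 9, 7796490 to 7888380), from 23.6 ± 16.9 to 0.584 ± 0.469 CPM (log2 fold change -5.34, SE 1.07, edgeR adjusted p = 0.0111), with 0.0697 in limma-voom, the highest of its alternatives, which begin at 1.94e-08. TMEM206, a proton-activated chloride channel, fell by 5.20, RNF24 by 4.17, the lysophosphatidylcholine acyltransferase gene LPCAT1 by 4.05 and the F-box gene FBXO25 by 4.03.

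Cytosolic ribosomal protein transcripts rose together: 57 of 74 members rose, 3 fell and 14 did not pass (58 and 3 adjusted over the list alone). Their summed level went from 67172 ± 1262 to 96092 ± 3181 CPM. RPL13A rose from 2533 ± 17.1 to 5083 ± 94.4 CPM (log2 fold change 1.00, SE 0.02, edgeR adjusted p = 5.74e-06) and RPL13 by 0.75, whereas RPS15 fell by 1.39 (edgeR adjusted p = 6.4e-06). The list passed camera at the preset correlation of 0.01 (adjusted p = 1.43e-16), and its camera adjusted p = 0.219 with an estimated correlation, which was 0.280. Replication-dependent histone transcripts rose in 25 of 49 members and fell in 3 (28 and 3 adjusted over the list alone). HIST1H3H, a core histone H3 gene (chromosome 6, 27810064 to 27811300), rose from 2.58 ± 0.206 to 38.3 ± 0.521 CPM (log2 fold change 3.89, SE 0.11, edgeR adjusted p = 2.62e-05). HIST1H2AE rose by 3.05 and the linker histone gene HIST1H1E fell by 3.74. The histone list passed camera (adjusted p = 0.000886; adjusted p = 0.206 with an estimated correlation). Both families hold near-identical copies or pseudogenes between which reads can be divided, so single members are uncertain.

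MYC and MYCN target transcripts fell in 22 of 50 members and rose in 7, the same numbers adjusted over the list alone (camera adjusted p = 0.00333; adjusted p = 0.198 with an estimated correlation). ODC1, the rate-limiting enzyme of polyamine synthesis, fell from 992 ± 17.1 to 565 ± 3.04 CPM (log2 fold change -0.81, SE 0.02, edgeR adjusted p = 1.58e-05), and the ribosome biogenesis gene PES1 rose by 0.42. Of 27 adrenergic neuroblastoma core regulators, 15 fell and 4 rose, the same adjusted over the list alone (camera adjusted p = 0.000562; adjusted p = 0.166 with an estimated correlation). INSM1, a neuroendocrine transcription factor, fell by 0.90 (edgeR adjusted p = 2.62e-05), while GATA3, a core factor of the adrenergic state, rose from 353.6 ± 5.52 to 819.6 ± 74.3 CPM (log2 fold change 1.21, SE 0.07, edgeR adjusted p = 0.000165). Neuronal differentiation genes fell in 15 of 39 members and rose in 2, the same adjusted over the list alone (camera adjusted p = 0.0191; adjusted p = 0.206 with an estimated correlation). The neuropeptide gene GAL fell from 103.8 ± 0.109 to 30.7 ± 2.56 CPM (edgeR adjusted p = 7.99e-05) and the neuronal tubulin gene TUBB3 fell by 0.65, while the neurotrophin receptor gene NTRK3 rose by 0.48. The neuronal list did not pass without OTSSP167 replicate 2 (camera adjusted p = 0.0806), in a range of 0.000221 to 0.206 over its alternatives, the lowest from fry. Of 25 mesenchymal neuroblastoma genes, 5 rose and 9 fell (6 and 9 adjusted over the list alone; camera adjusted p = 0.390), with a median of -0.23 and a mean of 0.16. NOTCH1 fell by 2.05 and COL5A1 by 1.66, and the intermediate filament gene VIM rose by 0.51.

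Metabolic transcripts mostly fell. In cholesterol biosynthesis, 15 of 24 members fell and 1 rose (15 and 2 adjusted over the list alone), with camera adjusted p = 0.000886 and adjusted p = 0.166 with an estimated correlation. HMGCS1, an early enzyme of the mevalonate pathway, fell from 444.5 ± 1.54 to 146.9 ± 3.07 CPM (log2 fold change -1.60, SE 0.03, edgeR adjusted p = 7.38e-06) and SQLE, which encodes squalene epoxidase, fell by 1.14. In glycolysis and hypoxia, 18 of 29 members fell and 4 rose (19 and 4 adjusted over the list alone), with camera adjusted p = 0.00104 and adjusted p = 0.219 with an estimated correlation. LDHA, also a member of the MYC list, fell from 751 ± 11.3 to 415 ± 4.11 CPM (edgeR adjusted p = 1.65e-05) and PGK1 fell by 0.92, while GAPDH rose by 0.38. Of 13 mitochondrially encoded transcripts, 9 fell and 0 rose in edgeR, the same adjusted over the list alone; 2 rose with upper-quartile scaling. MT-CO2 fell by 0.54 and MT-ATP8 by 0.32, and the list had camera adjusted p = 0.000886 and adjusted p = 0.367 with an estimated correlation. Mitochondrial counts were 4.13 to 4.34% of the DMSO libraries and 3.53 to 3.56% of the OTSSP167 libraries.

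Stress and cell cycle genes moved in both directions, and none of these lists passed camera. In the integrated stress and unfolded protein response, 19 of 37 members rose and 11 fell, the same adjusted over the list alone (camera adjusted p = 0.108); 19 rose and 6 fell with upper-quartile scaling. DDIT4, an inhibitor of mTORC1 signalling, rose from 87.2 ± 4.91 to 438.7 ± 3.13 CPM (log2 fold change 2.33, SE 0.05, edgeR adjusted p = 1.18e-05), and the transcription factor gene ATF4 rose by 1.47. HSPA5, the endoplasmic reticulum chaperone BiP, fell by 0.76. Of 17 heat shock genes, 3 rose and 6 fell, the same adjusted over the list alone (camera adjusted p = 0.0905, and 0.0432 without DMSO replicate 3, in a range of 0.000127 to 0.277 over its alternatives, the lowest from fry). HSP90AA1 fell from 3372 ± 53.5 to 2127 ± 16.5 CPM and FKBP4 by 0.64, while HSPA4 rose by 0.38. Of 57 G2/M and mitosis genes, 17 rose and 9 fell, the same adjusted over the list alone (camera adjusted p = 0.0813). TOP2A, the topoisomerase of mitotic chromosomes, rose from 843.6 ± 8.33 to 1688 ± 7.12 CPM (log2 fold change 1.00, SE 0.01, edgeR adjusted p = 5.74e-06), CDCA8 rose by 0.81 and HMMR fell by 0.67. Of 53 G1/S and DNA replication genes, 6 rose and 15 fell, the same adjusted over the list alone (camera adjusted p = 0.389); 10 rose and 13 fell with upper-quartile scaling. The replication licensing factor CDT1 rose from 143.5 ± 1.24 to 529.4 ± 14.1 CPM (log2 fold change 1.88, SE 0.03, edgeR adjusted p = 5.74e-06), while the primase-polymerase genes POLA2 and PRIM1 fell by 1.54 and 1.09. Of 45 p53 targets, 11 rose and 7 fell, the same adjusted over the list alone (camera adjusted p = 0.860). SESN2, a stress-induced inhibitor of mTORC1, rose by 2.47 and TP53INP1 by 1.32, and CDKN1A, the cell cycle inhibitor p21, fell from 83.6 ± 1.81 to 17.3 ± 0.836 CPM (log2 fold change -2.27, SE 0.07, edgeR adjusted p = 3.36e-05).

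**Figure D3:**
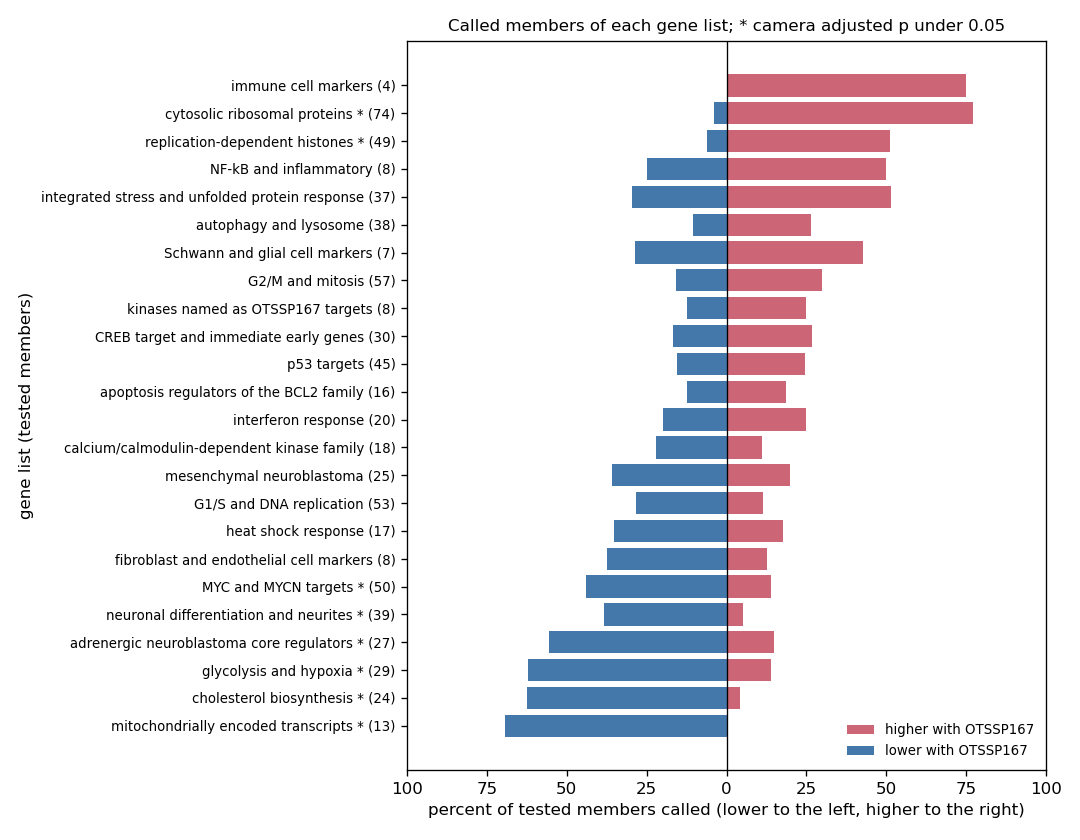
Bars give the percent of tested members of each of 24 gene lists that passed edgeR's test, higher to the right (red) and lower to the left (blue), with the number of tested members in parentheses. The 8 lists with an asterisk passed camera at its preset correlation, and 0 passed with an estimated one.

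The remaining lists had few called members or went both ways, and none that camera tested passed it. Of 16 BCL2 family genes, 3 rose and 2 fell, the same adjusted over the list alone, and BAD, a pro-apoptotic member, rose by 0.91 (camera adjusted p = 0.802 for the list, whose median was 0.07 and mean -0.02). With upper-quartile scaling, 5 of the BCL2 family genes rose and 2 fell. Of 38 autophagy and lysosome genes, 10 rose and 4 fell (7 and 4 adjusted over the list alone; camera adjusted p = 0.431); ATG16L1 rose by 0.86, TFE3 by 1.19, and HEXA fell by 0.68. Of 8 NF-kB and inflammatory genes, 4 rose and 2 fell, the same adjusted over the list alone (camera adjusted p = 0.756); RELB rose by 2.03 and NFKBIA by 0.45, while SOD2 fell by 1.27. Of 20 interferon response genes, 5 rose and 4 fell, the same adjusted over the list alone (camera adjusted p = 0.431). With upper-quartile scaling, 5 of them rose and 2 fell. IFI27 rose by 2.09. Markers of other cell types were also measured. Of 7 Schwann and glial markers, 3 rose and 2 fell (camera adjusted p = 0.756), of 8 fibroblast and endothelial markers 1 rose and 3 fell (0.625), and of 4 immune markers, too few for camera, 3 rose and 0 fell; all 3 counts were the same adjusted over the list alone. ERBB3 rose from 0.0884 ± 0.0781 to 6.85 ± 1.68 CPM and FOXD3 fell by 1.15. PDGFRB fell by 1.45, COL1A1 by 1.19, and THY1 rose by 1.24. CD14, a monocyte receptor gene, rose from 0.391 ± 0.122 to 14.2 ± 1.73 CPM (log2 fold change 5.17, SE 0.31, edgeR adjusted p = 0.000172) and CD74 from 0.664 ± 0.287 to 5.56 ± 1.29 CPM. CD14 (chromosome 5, 140631728 to 140633701) lies 5039 bp downstream of NDUFA2, a respiratory complex I gene on the same strand.

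**Figure D4:**
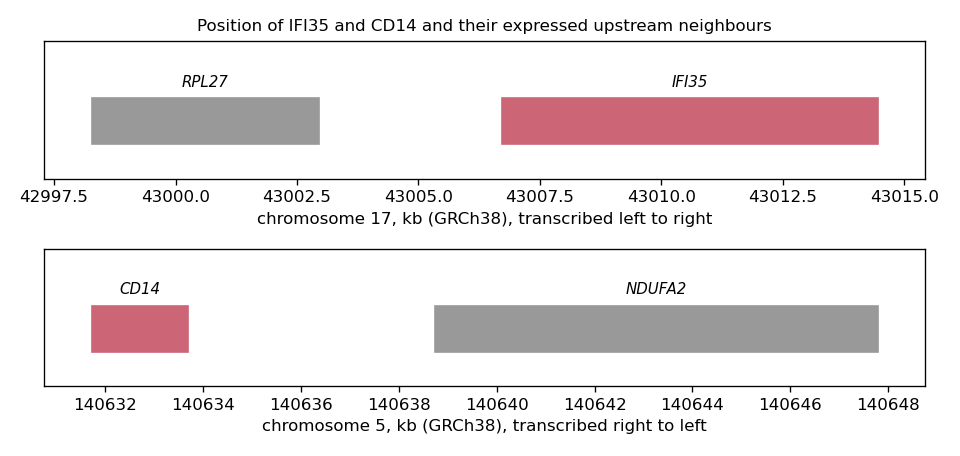
Gene spans in kb along GRCh38 for IFI35 with RPL27 (chromosome 17) and CD14 with NDUFA2 (chromosome 5), drawn to scale, with the gene that rose in red, its nearest expressed same-strand upstream neighbour in grey, and other genes not drawn. The gaps are 3766 and 5039 bp; NPR3, ERBB3 and CD74, the other named genes that rose at least 4-fold from under 1 CPM to 1 CPM or more, had no such neighbour within 10 kb.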

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

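The analysis without genes of scattered replicates was chosen after seeing the data, and the other settings were planned. It removes genes by their spread in these same libraries, which can lower the spread estimated for the remaining genes. Passes of genes and lists in that setting therefore add no support. The count of changed genes ran from 4887 (replicate block) to 8075 (DESeq2), and was 5540 to 5870 with single libraries left out. The split moved most with upper-quartile scaling, to 3935 higher and 2720 lower; that scaling raised the median log2 fold change of all genes to 0.11, from 0.01. The count past 1.5-fold was 1192 against a fold of 2, which asks for a larger change, 2887 with DESeq2, 3109 without genes of scattered replicates, and 2021 to 2209 with single libraries left out. It was 1496 with the replicate number as a block, which spends degrees of freedom. More of these genes were lower than higher with the block (737 higher, 759 lower), with at least 1 CPM in the 6 libraries (946 and 1019) and without any 1 OTSSP167 library, against 1526 higher and 1300 lower with all libraries. Same-numbered libraries deviated together by correlations of only 0.02, 0.04 and 0.01, too small to count as pairs. Each of the 6 correlated best with its own number. The deviations were taken from the group means, so these matches depend on one another. They are at most a weak hint from the data, and the design names no pairs. With the block the neuronal list (adjusted p = 0.0543) and CALM3 (0.0848) did not pass.

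Of the 23 lists, 8 passed camera with the preset correlation, 7 to 9 with single libraries left out, 7 with the block and 9 without genes of scattered replicates, when G2/M and mitosis passed (adjusted p = 0.0295). With an estimated correlation 0 passed camera, the lowest adjusted p being 0.166, with 5 at an unadjusted p under 0.05. For 4 of the 8 the estimated correlation was under the preset 0.01. Their calls ended because camera then tests with the 4 residual degrees of freedom of the libraries. The estimate was above the preset for the ribosomal (0.280), mitochondrial (0.441), glycolysis (0.0602) and histone (0.0261) lists. If these estimates hold, camera's p-values at the preset are too small for those lists. Fry, which compares no list with other genes, passed 20. Its direction was higher for G1/S and DNA replication, where camera's was lower, and lower for the p53 targets, where camera's was higher; fry did not pass either.

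MELK ran from -1.14 to 0.11 with single libraries left out and did not pass in any of these. Its OTSSP167 libraries 1 to 3 measured 17.2, 40.3 and 6.93 CPM. The sign turned when replicate 3, the lowest of these, was left out. The cause of this scatter was not tested. The depth limits the genes near 0 in one group, where 148 tested genes had no count in the 3 DMSO libraries and 8 none in the 3 OTSSP167 libraries.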

Other observations

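The 5 gene lists of the next paragraph, and the tests of a single poor library, of a larger share of cells in S phase, and of neighbours against all low genes, were chosen only after the data had been seen. Some members of these lists were among the values seen, so the counts below describe the lists, and no list test is given for them. The named members are those with the largest rise and fall that passed edgeR's test, with a few others.

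Of 20 transcripts of translation factors and other genes with a 5' terminal oligopyrimidine tract, the motif that ribosomal protein transcripts also carry, 13 rose and 4 fell. EEF2, the elongation factor, rose from 5649 ± 24.9 to 12634 ± 154 CPM (n = 3, edgeR adjusted p = 1.26e-06), EIF4B by 1.46 on the log2 scale and EEF1A1 by 0.61. The 4 that fell were EIF2S3, from 148.2 ± 17.9 to 32.2 ± 9.42 CPM (log2 fold change -2.20, edgeR adjusted p = 0.00168), HNRNPA1 (-1.04), EIF3K (-0.30) and PABPC1 (-0.25). Of 41 nuclear-encoded respiratory chain transcripts, 23 fell and 5 rose. NDUFS6, of complex I, had a log2 fold change of -3.48 and UQCRC2, of complex III, of -2.65, CYCS, which encodes cytochrome c, fell from 218.7 ± 8.60 to 111.6 ± 3.89 CPM, and UQCRB, also of complex III, rose by 0.84. Of 31 proteasome subunits, 16 fell and 4 rose, with PSMD4 at -1.27 and PSMC2 at 1.42 (SE 0.40, edgeR adjusted p = 0.0340). The OTSSP167 libraries of PSMC2 were scattered, at 50.4, 20.2 and 35.8 CPM. Of 23 nucleotide synthesis genes, 12 fell and 2 rose, with CTPS1 at -3.73 (SE 0.95, edgeR adjusted p = 0.0250) and MTHFD2 at 0.94. The DMSO libraries of CTPS1 were scattered, at 45.9, 178.7 and 155.0 CPM. Of 20 cytosolic aminoacyl-tRNA synthetases, 9 fell and 3 rose, with DARS at -3.53 and SARS at 1.17.

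More genes had reads in the OTSSP167 libraries, 15481 to 15900 against 14919 to 15030. Of 2203 tested genes under 1 CPM in DMSO, 510 came on, that is, passed the test at 4-fold or more and reached 1 CPM, while 76 went the opposite way. After thinning to 1 total the lowest OTSSP167 library still had 505 more genes than the highest DMSO library, against a range of at most 357 within a group, which argues against depth. Of the 489 protein-coding genes that came on and had coordinates, 121 (24.7%) had an expressed same-strand gene ending within 10 kb upstream, against 11.4% of 1237 low genes not called higher (odds ratio 2.55, 95% interval 1.93 to 3.38, Fisher's exact test) and 12.7% of all 1588 low genes that did not come on (2.26, 1.73 to 2.92), whereas a neighbour starting within 10 kb downstream (0.694, 0.463 to 1.02, against the 1237 genes) and overlap with an expressed gene (1.05, 0.799 to 1.37) were not more frequent. A candidate explanation for a part of these rises is transcription running on past the end of the upstream gene, but of the 5 named genes that came on only IFI35 (RPL27) and CD14 (NDUFA2) had such a neighbour within 10 kb, the nearest lying 84991 bp from NPR3, 32102 bp from ERBB3 and 29706 bp from CD74, and activation of the genes' own promoters stays open and was not tested.

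Single libraries of a group differed several fold in many abundant genes: of 6052 genes of at least 30 CPM, 1006 (16.6%) had a range over 2-fold within a group and 241 over 4-fold. CHGA, which encodes chromogranin A, measured 102, 293 and 598 CPM in the DMSO libraries. No library was the odd one out in more than 35.4% of them in its group, which argues against 1 poor library. The share was 10.7% among genes with 1 or 2 annotated transcripts and 17.4% among genes with 5 or more; at matched expression and exonic length the ratio was 1.26 (95% bootstrap interval 1.00 to 1.65). Reads divided between transcript models may thus contribute, but the interval keeps this open, and no biological explanation was tested.

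The rise of replication-dependent histone transcripts was not only a shift of reads among the listed copies. Their summed level rose 3.14-fold, from 118.8 ± 7.49 to 372.5 ± 28.8 CPM, with each OTSSP167 library (348 CPM or more) above each DMSO library (124 CPM or less). The sum does not cover copies outside the list or reads left uncounted, so a shift from these stays open. It also counts only the histone transcripts that the mRNA library kit captured. The share captured was not measured, so a change in that share stays open too. A larger share of cells in S phase would raise G1/S and DNA replication genes too; their median log2 fold change was -0.17, with members going both ways, so S phase cannot be told apart from other sources by these transcripts. The criterion here was changed after its value was seen: the first one, a median under 0 with more members lower (15) than higher (6), was met and would have ruled S phase out, while the later one, a fall of the list in camera, was not (adjusted p = 0.389). Of the 25 histone genes that rose, 2 had an expressed same-strand gene ending within 10 kb upstream. Effects of OTSSP167 on histone transcription or transcript ends stay open and were not tested.

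The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split alone, 1 of 10, gave 6638 changed genes, 2826 past 1.5-fold and 8 lists. The highest counts of the other splits were 1, 1 and 5. Each of the other splits passed 1 to 5 lists at camera's preset correlation. These splits mix treated and control libraries in both groups and still hold part of the treatment difference. That difference also enters their spread within groups, so low gene counts in them follow from the design. Neither their gene calls nor their list calls are a count of false ones.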
